A study of Homo sapiens with 8 samples.

How the data were processed

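The samples were cultures of HCT116, an established human colorectal carcinoma line, treated for 10 h with largazole at 20 nM, FK228 at 20 nM, SAHA at 2 µM or vehicle, with 2 Affymetrix U133 2.0 arrays per group and 8 in all. The deposited values are probe set levels on the log2 scale, with nearly equal medians on all arrays. The submitters' processing notes name affy, RMA and limma with no version, role or order, so which of them gave the values, and by which steps, is not given in the sources used here. The labels say only that the experiment was done in duplicate, so the p-values measure only the spread between these samples. The number of arrays limits the precision: the 95% confidence interval of a gene's log2 difference between groups had a median half-width of 0.24.

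The table holds 54613 probe sets and 0 AFFX controls. The platform's annotation gives exactly 1 gene symbol for 41091 of them, several for 1801 and none for 11721. Of the probe sets with 1 symbol, 41037 matched the RefSeq gene table by gene ID, and 0 symbols were updated. That table served only for names and for which genes neighbour each other. Probe sets were kept when their second-highest value over the 8 arrays reached the median of all values (4.49), a filter blind to group, which left 28985. A gene stands for its probe set with the highest mean over the arrays among those with exactly 1 symbol, which gave 13381 genes from 24585 named probe sets.

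The arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 coefficient per group and empirical Bayes moderation (4 residual degrees of freedom, 3.69 prior degrees of freedom). Benjamini-Hochberg adjustment ran over the tested probe sets of each of the 6 comparisons, and an adjusted p under 0.05 was called. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so no single-gene permutation test was run. Tables and figures were prepared with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

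Designs, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Named genes are the 10 largest rises and 10 largest falls with each compound among called genes whose 2 treated arrays both lay outside the 2 vehicle arrays, and for each pair of compounds up to 5 genes highest in each. Added to these are a fixed panel (CDKN1A, CDKN1B, CCND1, CCNE1, MYC, EGFR, ERBB2, ERBB3, MET, IGF1R, INSR, HDAC1, HDAC3, HDAC5, MDM2, BCL2L1, MCL1 and TYMS) and up to 2 highest and 2 lowest members of each list.

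The 36 gene lists covered CDK inhibitors, cyclins and their kinases, DNA replication, mitosis, homologous recombination repair, p53 targets, pro-apoptotic genes, anti-apoptotic genes, growth factor receptors, HDAC genes, acetyltransferases and bromodomain readers, histone genes, metallothioneins, neuronal genes, germline genes, cholesterol synthesis, Wnt targets, ribosome biogenesis, ribosomal proteins, intestinal differentiation, epithelial junctions, mesenchymal genes, cytoskeleton, antigen presentation, interferon-stimulated genes, heat shock, the unfolded protein and ATF4 response, the thioredoxin and NRF2 response, glycolysis, oxidative phosphorylation, lysosome and autophagy, immediate-early genes and chromatin repressors. The remaining lists held markers of leukocytes, of fibroblasts and endothelium, and of other epithelial lines, which an HCT116 culture should lack. Counts given for a list cover only its members among the tested genes, which for some lists are a minority of the fixed members. Each list was compared with the other genes by camera with a preset correlation of 0.01, with camera's estimated correlation beside it, and tested on its own by fry. The adjustment ran over all 216 tests of lists and comparisons.

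Changes with different compounds were correlated across genes. Since the comparisons share their vehicle arrays, 100 simulations with no change gave the correlation that shared controls produce, and each compound was also set against a different vehicle array. The overlap of calls was compared with n1 × n2 / N per direction.

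The alternatives were no filter, a stricter filter at 6.87, an intensity trend with a robust prior, replicate number as a replicate block, array weights, equal medians of the ribosomal protein genes, a further quantile normalization, probe sets with names ending in _x_at or _s_at left out, the mean of all probe sets of a gene, the estimated correlation, only the 4 arrays of the 2 groups compared, and each array left out in turn. With an array left out, the lone array of its group was assumed to vary like the other groups.

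In data simulated for largazole against vehicle, 50 of 28985 probe sets changed per size. The fit recovered 1 at 1.2-fold, 26 at 1.5-fold, 49 at 2-fold and 50 at 4-fold, with 8 false among 134 calls. The data gave 11790 calls, a laxer cut-off, so these rates do not carry over. Probe sets without exactly 1 symbol entered probe set counts only. Viability, protein levels and histone acetylation were not analysed.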

Results

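Gene expression was measured on Affymetrix arrays in HCT116 colorectal carcinoma cells exposed for 10 h to 1 of 3 histone deacetylase inhibitors or to vehicle. Largazole, a cyclic depsipeptide that carries a thioester, and FK228 (romidepsin), a bicyclic depsipeptide that carries a disulfide, were both given at 20 nM. SAHA (vorinostat), a hydroxamic acid, was given at 2 µM. Each of the 4 groups held 2 arrays. Median log2 signal lay between 4.47 and 4.51 on the 8 arrays, and values ran from 1.71 to 14.67. The comparisons ask which transcripts each inhibitor changed against vehicle, and at which transcripts the inhibitors differed.

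The treated arrays separated from the vehicle arrays on the first principal component, which held 75.8% of the variance. The vehicle arrays stood at 76.8 and 78.1 on that axis, the largazole arrays at -16.5 and -15.8, the SAHA arrays at -21.2 and -20.9, and the FK228 arrays at -40.7 and -39.7. Across all probe sets, Pearson's r was 0.995 to 0.997 between the 2 arrays of a group, 0.993 to 0.996 between arrays of different compounds and 0.975 to 0.984 between treated and vehicle arrays. Probe sets are not independent replicates.

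**Figure D1:**
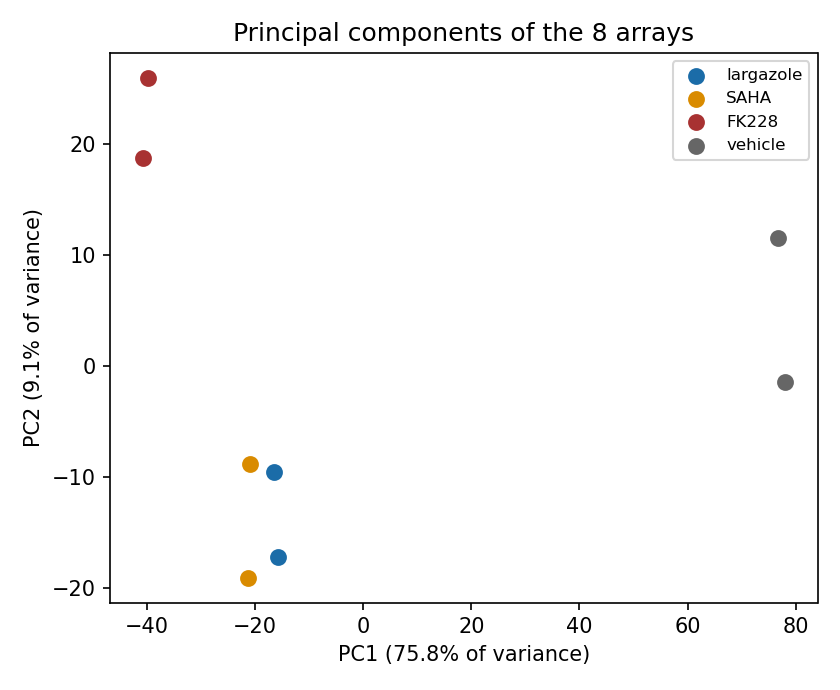
Each point is 1 array, placed by its first (PC1) and second (PC2) principal component scores and coloured by group. The vehicle arrays lie at 76.8 and 78.1 on PC1 and the 6 treated arrays between -40.7 and -15.8.

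Largazole raised DHRS2, a short-chain dehydrogenase/reductase, from a log2 level of 7.59 to 12.50, a change of 4.92 ± 0.10 (SE, n = 2). NEDD9, a focal adhesion scaffold, rose by 4.12 ± 0.15, SNAI2, the transcriptional repressor Slug, by 3.96 ± 0.17, SYT11, a vesicle-trafficking synaptotagmin, by 3.89 ± 0.13 and IGFBP3, which binds insulin-like growth factors, by 3.74 ± 0.15. ENPP2, the lysophosphatidic acid-producing enzyme autotaxin, followed at 3.64 ± 0.15, with HEY1, a Notch-responsive repressor, at 3.56 ± 0.12. ZCCHC12 (3.52 ± 0.084), the chemokine receptor CXCR4 (3.43 ± 0.11) and the TNF receptor family member TNFRSF19 (3.40 ± 0.11) complete the 10 largest rises.

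The largest fall with largazole was that of PDE4B, a cAMP phosphodiesterase, at -4.83 ± 0.12 (SE, n = 2). HMGA2, an architectural chromatin protein, changed by -4.25 ± 0.15, the protocadherin PCDH7 by -4.13 ± 0.14 and the homeobox gene MKX by -4.08 ± 0.14. The epithelial ETS factor EHF changed by -3.59 ± 0.11, the nuclear receptor corepressor NRIP1 by -3.11 ± 0.13 and the homeobox gene HOXB8 by -3.07 ± 0.19. ZBED2 (-3.92), ITPRIPL2 (-3.85) and FAM83B (-3.11) were the other members of the 10 largest falls. Adjusted p was at most 2.32e-05 (HOXB8, limma) for these 20 genes, and each kept its call with any array left out. With all probe sets of a gene averaged, the change was 2.58 for NEDD9, 1.68 for TNFRSF19, -2.39 for HMGA2 and -2.05 for EHF. HMGA2 was at -1.503 without probe sets named _x_at or _s_at, and with the 4 arrays of the 2 groups alone another probe set stood for NEDD9 (1.04) and IGFBP3 (1.43). Levels under the filter value of 4.49, near background, were those of NEDD9 (2.31), SNAI2 (3.38), SYT11 (3.22), IGFBP3 (3.36), ENPP2 (2.58) and TNFRSF19 (3.89) with vehicle and MKX and ZBED2 with largazole, so the sizes and ranks of these changes are less certain.

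Among cell cycle genes of the fixed panel, the CDK inhibitor CDKN1A rose by 0.86 ± 0.091 with largazole (SE, n = 2), while the CDK inhibitor CDKN1B (-1.04 ± 0.12) and cyclin D1, CCND1 (-1.01 ± 0.086), fell. The receptor tyrosine kinases EGFR (-0.92), ERBB2 (-1.19), ERBB3 (-0.997) and MET (-1.34) fell and IGF1R rose (1.08), whereas INSR was not called (-0.0019, adjusted p = 0.988). The survival gene BCL2L1 (-1.16) and thymidylate synthase, TYMS (-0.73), fell, and MCL1 (0.54), HDAC3 (0.50) and HDAC5 (0.41) rose. HDAC1 (0.18, adjusted p = 0.142) and MDM2 (-0.16, adjusted p = 0.504) were not called. MYC fell by 0.31 and CCNE1 fell by 0.27. The call of HDAC5 ended without largazole replicate 2 (adjusted p = 0.0884) or vehicle replicate 1 (adjusted p = 0.0795), that of MYC without largazole replicate 1, largazole replicate 2, vehicle replicate 1 or vehicle replicate 2 (adjusted p = 0.0805 to 0.152), and that of CCNE1 without largazole replicate 1, largazole replicate 2, SAHA replicate 1, SAHA replicate 2, FK228 replicate 1, FK228 replicate 2 or vehicle replicate 2 (adjusted p = 0.0516 to 0.199). Of the probe sets tested, 4 of 8 for EGFR and 1 of 2 for ERBB2 had this sign, and the means over all probe sets were -0.34 for EGFR, -0.53 for ERBB2, 0.62 for IGF1R and -0.72 for BCL2L1. INSR was called at 0.52 without probe sets named _x_at or _s_at (adjusted p = 0.00473).

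In all, largazole changed 6044 of 13381 genes, 2936 higher and 3108 lower, a balance that turned to 3149 and 2779 at equal ribosomal protein medians and 3087 and 2925 after a further quantile normalization. Of these, 582 rose and 638 fell at least 2-fold, against 629 and 600 at equal ribosomal protein medians. By probe set, 11790 of 28985 were called, 5674 higher and 6116 lower (47.1 to 52.8% higher over all settings, the highest at equal ribosomal protein medians). The count was 7125 with probe sets named _x_at or _s_at left out, which leaves fewer probe sets to test.

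Gene lists that fell with largazole included those of cell division and chromatin. Of 40 mitosis and spindle checkpoint genes, 20 fell and 1 rose (21 and 2 adjusted over the list alone), with AURKA, a mitotic kinase, at -1.13 and the kinetochore gene NDC80 at -0.98. Their median was -0.34 (camera adjusted p = 0.000756, adjusted p = 0.314 with an estimated correlation). Of 25 ribosome biogenesis genes, 15 fell and 1 rose (18 and 1 adjusted over the list alone), with UTP20 (-1.20) and NIP7 (-0.99) lowest. Their median was -0.29 (camera adjusted p = 0.00255, adjusted p = 0.314 with an estimated correlation). Of 24 chromatin repressor and DNA methyltransferase genes, 13 fell and 0 rose (15 and 0 adjusted over the list alone), with MBD3 (-0.88) and SETDB1, a histone methyltransferase (-0.85), lowest. Their median was -0.33 (camera adjusted p = 0.00941, adjusted p = 0.327 with an estimated correlation). Of 15 acetyltransferase and bromodomain genes, 8 fell and 0 rose (the same adjusted over the list alone), with BRD1 (-1.16) and the acetyltransferase KAT5 (-0.99) lowest. Their median was -0.41 (camera adjusted p = 0.0241, adjusted p = 0.348 with an estimated correlation). Of 14 cyclin, CDK and CDC25 genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone), with CDK6 at -0.67 and cyclin D3, CCND3, higher by 1.17. Their median was -0.32 (camera adjusted p = 0.0399, adjusted p = 0.358 with an estimated correlation). This last call ended without largazole replicate 2 (adjusted p = 0.0636) or vehicle replicate 1 (adjusted p = 0.0582).

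Lists that rose with largazole included sterol synthesis and histone genes. Of 19 cholesterol synthesis and uptake genes, 14 rose and 0 fell (15 and 1 adjusted over the list alone), with INSIG1, a regulator of sterol synthesis, at 2.02 and the isomerase IDI1 at 1.24. Their median was 0.58 (camera adjusted p = 0.000756, adjusted p = 0.314 with an estimated correlation). Of 12 histone genes with polyadenylated transcripts, 8 rose and 0 fell (the same adjusted over the list alone), with H2BC5 at 1.98 and H2AC6 at 1.79. Their median was 1.17 (camera adjusted p = 0.00398, adjusted p = 0.380 with an estimated correlation). Of 23 actin and microtubule regulators, 12 rose and 2 fell (13 and 2 adjusted over the list alone), with MAP1LC3B (1.49) and the tubulin TUBA1A (1.46) highest and CFL2, an actin-severing cofilin (-0.66), lowest. Their median was 0.29 (camera adjusted p = 0.0104, adjusted p = 0.316 with an estimated correlation). Of 29 lysosome and autophagy genes, 14 rose and 2 fell (15 and 2 adjusted over the list alone), with the sialidase NEU1 at 2.48 and the cholesterol transporter NPC1 at 1.497. Their median was 0.23 (camera adjusted p = 0.0119, adjusted p = 0.583 with an estimated correlation). Of 25 neuronal and synaptic genes, 13 rose and 1 fell (the same adjusted over the list alone), with SYT11 at 3.89 and the microtubule-binding gene MAP2 at 2.58. Their median was 0.30 (camera adjusted p = 0.0123, adjusted p = 0.358 with an estimated correlation). Of 6 metallothioneins, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with MT1X and MT1F both at 0.50. Their median was 0.33 (camera adjusted p = 0.0325, adjusted p = 0.426 with an estimated correlation). The metallothionein call ended without largazole replicate 2 (adjusted p = 0.0646) or vehicle replicate 1 (adjusted p = 0.0582). Leaving out probe sets named _x_at or _s_at ended the calls of the acetyltransferase (0.217), histone (0.10), neuronal (0.10), cytoskeleton (0.0658), lysosome (0.0514), cyclin (0.10) and chromatin repressor (0.10) lists, with adjusted p in parentheses. The stricter filter ended the cyclin (0.0924) and metallothionein (0.0568) calls, and moved the neuronal median to 0.52 and the cytoskeleton median to 0.46.

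SAHA, at its higher dose, also raised DHRS2 most, by 4.87 ± 0.10 (SE, n = 2), to a log2 level of 12.46. NEDD9 (4.01 ± 0.15), SNAI2 (3.65 ± 0.17), HEY1 (3.52 ± 0.12), ENPP2 (3.29 ± 0.15), ZCCHC12 (3.30 ± 0.084) and TNFRSF19 (3.30 ± 0.11) were again among the 10 largest rises. The remaining 3 were SSBP2, a single-stranded DNA-binding protein (3.32 ± 0.14), PAG1, an adaptor that recruits the kinase CSK (3.25 ± 0.090), and the cytolinker gene EPPK1 (3.18 ± 0.099). The largest falls were those of PDE4B (-5.79 ± 0.12), HMGA2 (-5.02 ± 0.15), MKX (-4.57 ± 0.14), PCDH7 (-4.24 ± 0.14) and ZBED2 (-4.24 ± 0.12). EHF (-4.08), ITPRIPL2 (-3.99), the vitamin D hydroxylase CYP24A1 (-3.58), FAM83B (-3.22) and JADE2 (-3.08) followed. Averaging all probe sets of a gene gave 2.48 for NEDD9, 2.16 for SSBP2, 1.63 for TNFRSF19, 1.87 for EPPK1, -2.71 for HMGA2, -2.43 for EHF and -1.96 for JADE2. HMGA2 was at -1.51 without probe sets named _x_at or _s_at, and NEDD9 at 0.94 with 4 arrays alone. The sizes and ranks are less certain where a level lay under the filter value of 4.49, as for NEDD9 (2.31), SNAI2 (3.38), TNFRSF19 (3.89) and ENPP2 (2.58) with vehicle and MKX (3.16), ZBED2 (3.28) and EHF (4.44) with SAHA.

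In the panel, SAHA raised CDKN1A by 0.95 ± 0.091 (SE, n = 2) and IGF1R by 1.11 ± 0.092, and lowered CDKN1B (-1.02), CCND1 (-1.06) and MYC (-0.51). EGFR (-0.69, mean of all probe sets -0.31), ERBB2 (-1.22, mean of all probe sets -0.51), ERBB3 (-0.999) and MET (-1.35) fell, as did BCL2L1 (-1.13, mean of all probe sets -0.69) and TYMS (-0.86). MCL1 (0.66), HDAC3 (0.69) and HDAC5 (0.32) rose, and the HDAC5 call ended without SAHA replicate 1 (adjusted p = 0.0734), SAHA replicate 2 (0.111) or vehicle replicate 1 (0.169). CCNE1 (-0.11, adjusted p = 0.370), INSR (0.19, adjusted p = 0.118), HDAC1 (0.12, adjusted p = 0.306) and MDM2 (-0.16, adjusted p = 0.484) were not called, though INSR was at 0.52 and called without probe sets named _x_at or _s_at (adjusted p = 0.00436).

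SAHA changed 6339 genes, 2963 higher and 3376 lower, a balance that turned to 3204 and 3033 at equal ribosomal protein medians. At least 2-fold, 574 rose and 753 fell. By probe set, 12666 were called, 6295 higher and 6371 lower (49.3 to 54.6% higher over all settings, the highest at equal ribosomal protein medians), and 7612 were called with probe sets named _x_at or _s_at left out.

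Cell division and chromatin lists also fell with SAHA. Of 40 mitosis genes, 22 fell and 2 rose (the same adjusted over the list alone), with the transcription factor FOXM1 at -1.06 and AURKA at -1.05. Their median was -0.31 (camera adjusted p = 0.00297, adjusted p = 0.314 with an estimated correlation). Of 25 ribosome biogenesis genes, 15 fell and 1 rose (18 and 2 adjusted over the list alone), with UTP20 at -1.24. Their median was -0.35 (camera adjusted p = 0.00846, adjusted p = 0.316 with an estimated correlation). Of 15 acetyltransferase and bromodomain genes, 9 fell and 0 rose (the same adjusted over the list alone), with BRD1 at -1.18. Their median was -0.57 (camera adjusted p = 0.0165, adjusted p = 0.346 with an estimated correlation). Of 24 chromatin repressor genes, 11 fell and 0 rose (13 and 0 adjusted over the list alone), with MBD3 at -1.13. Their median was -0.30 (camera adjusted p = 0.0165, adjusted p = 0.348 with an estimated correlation). The chromatin repressor call ended without vehicle replicate 1 (adjusted p = 0.0669). Of 19 cholesterol genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone), with INSIG1 at 2.05. Their median was 0.59 (camera adjusted p = 0.000756, adjusted p = 0.314 with an estimated correlation). Of 12 histone genes, 8 rose and 0 fell (8 and 1 adjusted over the list alone), with H2BC4 at 1.74. Their median was 0.99 (camera adjusted p = 0.00941, adjusted p = 0.402 with an estimated correlation). Of 23 actin and microtubule regulators, 15 rose and 3 fell (15 and 5 adjusted over the list alone), with TUBA1A at 1.53. Their median was 0.42 (camera adjusted p = 0.0113, adjusted p = 0.316 with an estimated correlation). Of 6 metallothioneins, 6 rose and 0 fell (the same adjusted over the list alone), with MT1F at 0.63. Their median was 0.42 (camera adjusted p = 0.0123, adjusted p = 0.402 with an estimated correlation). Of 29 lysosome and autophagy genes, 13 rose and 2 fell (14 and 2 adjusted over the list alone), with NEU1 at 2.59. Their median was 0.15 (camera adjusted p = 0.0279, adjusted p = 0.648 with an estimated correlation). The lysosome median was 0.23 without SAHA replicate 1, and without SAHA replicate 2 it was 0.091 and the call ended (adjusted p = 0.0781). Cyclins (camera adjusted p = 0.180, 1 rose and 6 fell, the same counts adjusted over the list alone) and neuronal genes (camera adjusted p = 0.0784, 9 rose and 2 fell, the same counts adjusted over the list alone) were not called as lists, and the neuronal list was called without SAHA replicate 1 (adjusted p = 0.0422). Leaving out probe sets named _x_at or _s_at ended the calls of the mitosis (0.0564), acetyltransferase (0.200), histone (0.10), cytoskeleton (0.10), lysosome (0.10) and chromatin repressor (0.124) lists, with adjusted p in parentheses. With the stricter filter the histone (0.0568), lysosome (0.0817) and chromatin repressor (0.0615) calls ended, and with the mean of all probe sets the cytoskeleton median was 0.26 and the neuronal list was called (adjusted p = 0.0455).

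With FK228 the largest rises were those of SYT11 (4.92 ± 0.13, SE, n = 2) and DHRS2 (4.88 ± 0.10). NEDD9 (4.18 ± 0.15), TNFRSF19 (4.02 ± 0.11), SNAI2 (3.98 ± 0.17), IGFBP3 (3.91 ± 0.15), ENPP2 (3.87 ± 0.15) and HEY1 (3.81 ± 0.12) were joined by the secreted protein gene CRISPLD2 (3.99 ± 0.098) and by PMEPA1, a TGF-beta-induced membrane protein (3.96 ± 0.15). PDE4B fell furthest, to a log2 level of 3.598 from 10.34 (-6.74 ± 0.12), followed by HMGA2 (-5.96 ± 0.15), PCDH7 (-5.65 ± 0.14) and MKX (-5.04 ± 0.14). CYP24A1 (-4.86), NRIP1 (-4.82), EHF (-4.74), ITPRIPL2 (-4.42), FAM83B (-4.18) and EREG, the EGFR ligand epiregulin (-4.17), completed the 10 largest falls. Averaging all probe sets of a gene gave 2.70 for NEDD9, 2.16 for TNFRSF19, 2.11 for CRISPLD2, -2.94 for HMGA2, -3.51 for PCDH7 and -2.79 for EHF. HMGA2 was at -1.44 without probe sets named _x_at or _s_at, and with 4 arrays alone NEDD9 was at 1.21 and IGFBP3 at 1.42. With FK228 the levels of PDE4B (3.598), HMGA2 (4.10), MKX (2.69), NRIP1 (4.35), EHF (3.79) and FAM83B (3.61) lay under the filter value of 4.49, as did those of SYT11 (3.22), NEDD9 (2.31), TNFRSF19 (3.89), SNAI2 (3.38), PMEPA1 (4.02), IGFBP3 (3.36) and ENPP2 (2.58) with vehicle, so the sizes and ranks of these changes are less certain.

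FK228 raised CDKN1A by 0.94 ± 0.091 (SE, n = 2) and CCNE1, cyclin E1, by 0.38 ± 0.088, and lowered CDKN1B (-1.85 ± 0.12), CCND1 (-1.48 ± 0.086), MYC (-1.34 ± 0.094) and the p53 regulator MDM2 (-0.86 ± 0.17). The CCNE1 call ended without vehicle replicate 1 (adjusted p = 0.0580), and the MDM2 value was -0.41 with probe sets named _x_at or _s_at left out. EGFR (-1.29, mean of all probe sets -0.51), ERBB2 (-1.20, mean of all probe sets -0.48), ERBB3 (-1.08), MET (-1.61), BCL2L1 (-1.57, mean of all probe sets -0.995) and TYMS (-0.65) fell. IGF1R (0.85, mean of all probe sets 0.47), MCL1 (0.85), HDAC3 (0.72) and HDAC5 (0.44) rose. INSR (0.14, adjusted p = 0.224) and HDAC1 (0.16, adjusted p = 0.176) were not called, though INSR was at 0.51 and called without probe sets named _x_at or _s_at (adjusted p = 0.00382).

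FK228 changed 7060 genes, 3440 higher and 3620 lower, a balance that turned to 3629 and 3362 at equal ribosomal protein medians and 3527 and 3520 after a further quantile normalization. At least 2-fold, 826 rose and 1031 fell. By probe set, 14195 were called, 7045 higher and 7150 lower (48.2 to 53.1% higher over all settings, the highest at equal ribosomal protein medians), and 8592 with probe sets named _x_at or _s_at left out.

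Of 40 mitosis genes, 28 fell and 1 rose (31 and 1 adjusted over the list alone), with NDC80 at -1.38 and the kinase PLK1 at -1.29. Their median was -0.55 (camera adjusted p = 1.18e-05, adjusted p = 0.314 with an estimated correlation). Of 24 chromatin repressor genes, 15 fell and 0 rose (16 and 0 adjusted over the list alone), with SETDB1 at -1.23 and the DNA methyltransferase DNMT3A at -1.15. Their median was -0.40 (camera adjusted p = 0.00680, adjusted p = 0.316 with an estimated correlation). Of 15 acetyltransferase and bromodomain genes, 9 fell and 0 rose (11 and 0 adjusted over the list alone), with BRD1 at -1.69. Their median was -0.67 (camera adjusted p = 0.0107, adjusted p = 0.316 with an estimated correlation). Of 19 cholesterol genes, 15 rose and 0 fell (the same adjusted over the list alone), with INSIG1 at 2.57 and IDI1 at 1.79. Their median was 0.70 (camera adjusted p = 0.000449, adjusted p = 0.314 with an estimated correlation). Of 25 neuronal genes, 15 rose and 2 fell (the same adjusted over the list alone), with SYT11 at 4.92 and MAP2 at 2.31. Their median was 0.36 (camera adjusted p = 0.0123, adjusted p = 0.358 with an estimated correlation). Of 29 lysosome and autophagy genes, 15 rose and 2 fell (15 and 3 adjusted over the list alone), with NEU1 at 3.07 and NPC1 at 1.99. Their median was 0.23 (camera adjusted p = 0.0259, adjusted p = 0.637 with an estimated correlation). Of 12 histone genes, 9 rose and 0 fell (the same adjusted over the list alone), with H2BC5 at 1.76. Their median was 0.90 (camera adjusted p = 0.0270, adjusted p = 0.427 with an estimated correlation). Of 23 actin and microtubule regulators, 13 rose and 3 fell (the same adjusted over the list alone), with the tubulin TUBB4A at 1.53. Their median was 0.45 (camera adjusted p = 0.0443, adjusted p = 0.358 with an estimated correlation). This last call ended without SAHA replicate 1 (adjusted p = 0.0524) and with replicate number as a replicate block (adjusted p = 0.0564). Ribosome biogenesis genes (3 rose and 12 fell, 3 and 14 adjusted over the list alone, camera adjusted p = 0.153), metallothioneins (3 rose and 0 fell, the same adjusted over the list alone, camera adjusted p = 0.131) and cyclins (2 rose and 8 fell, 3 and 8 adjusted over the list alone, camera adjusted p = 0.191) were not called as lists. The calls of the acetyltransferase (0.175), histone (0.225), neuronal (0.10), cytoskeleton (0.10), lysosome (0.10) and chromatin repressor (0.0870) lists ended without probe sets named _x_at or _s_at, with adjusted p in parentheses. Those of the histone (0.0912), neuronal (0.0550) and cytoskeleton (0.116) lists ended with the stricter filter, and that of the cytoskeleton list also with the mean of all probe sets (0.0670).

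**Figure D2:**
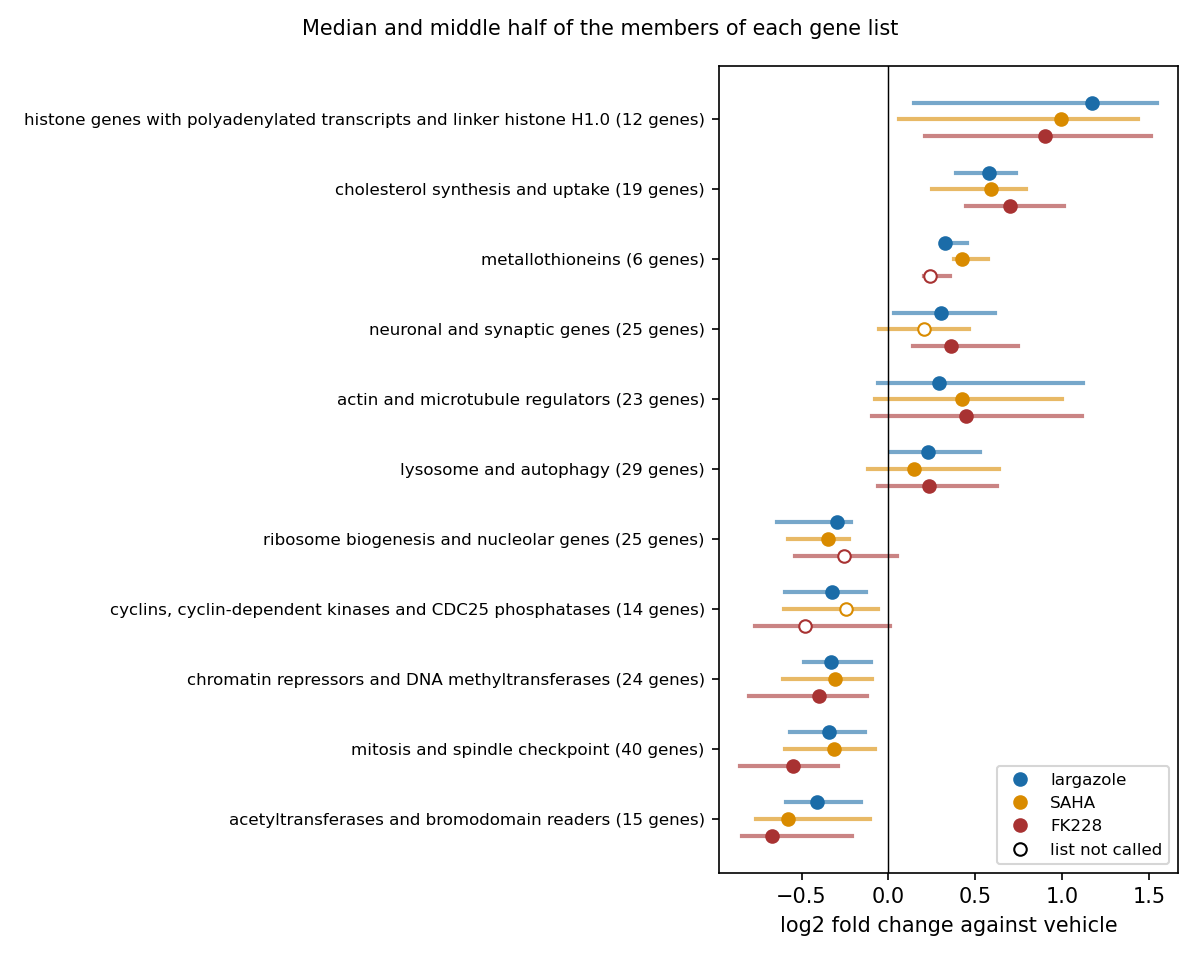
Dots are the median log2 change against vehicle of each list's members and lines span the middle 50% of members, for the 11 lists called with at least 1 compound, with open dots where the list was not called. Medians run from -0.67 for acetyltransferases and bromodomain readers with FK228 to 1.17 for histone genes with largazole.

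No other list was called against vehicle. Numbers run in the order largazole, SAHA and FK228, which changed 45.2, 47.4 and 52.8% of all genes, the background to member counts. Of the 6 CDK inhibitor genes, 4 rose and 2 fell with each compound (the same adjusted over the list alone, camera adjusted p = 0.283, 0.281 and 0.317). CDKN2D rose by 1.70, 1.79 and 2.46 and CDKN1B changed by -1.04, -1.02 and -1.85. Of the 43 DNA replication genes, 7 rose with each compound and 16, 17 and 21 fell (7, 7 and 7 higher and 17, 17 and 21 lower adjusted over the list alone, camera adjusted p = 0.0749, 0.129 and 0.131). The licensing gene CDC6 rose by 0.70, 0.83 and 0.98, whereas the polymerase subunit gene POLE2 changed by -1.01, -1.09 and -1.21. Without the filter this list was called with each compound (adjusted p = 0.0260, 0.0492 and 0.0433). Of the 23 homologous recombination genes, 4, 7 and 7 rose and 9, 10 and 12 fell (5, 7 and 7 higher and 9, 11 and 12 lower adjusted over the list alone, camera adjusted p = 0.298, 0.589 and 0.589). FANCB rose by 0.86, 1.25 and 0.92, and FANCL, a ubiquitin ligase of the Fanconi pathway, changed by -0.89, -1.41 and -1.68. Of the 23 p53 targets, 9, 10 and 9 rose and 6 fell with each compound (11, 11 and 9 higher and 6, 6 and 6 lower adjusted over the list alone, camera adjusted p = 0.298, 0.279 and 0.637). The kinase gene PLK3 rose by 1.21, 1.28 and 1.40, and the death receptor FAS changed by -2.08, -2.09 and -2.41. Of the 20 pro-apoptotic genes, 4, 5 and 6 rose and 9, 10 and 9 fell (the same adjusted over the list alone, camera adjusted p = 0.560, 0.686 and 0.611). BCL2L11, the BH3-only protein BIM, rose by 1.63, 1.67 and 1.63, and CASP8, an initiator caspase, changed by -1.10, -1.08 and -1.58. Of the 8 anti-apoptotic genes, 2, 2 and 1 rose and 5 fell with each compound (the same adjusted over the list alone, camera adjusted p = 0.320, 0.423 and 0.272). CFLAR, an inhibitor of CASP8, changed by -1.88, -2.04 and -2.21. Of the 18 growth factor receptor genes, 7, 6 and 6 rose and 8, 9 and 8 fell (the same adjusted over the list alone, camera adjusted p = 0.904, 0.764 and 0.705). EPHB3 rose by 1.66, 1.36 and 1.60, and the adaptor IRS1 changed by -2.44, -2.63 and -3.21.

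Of the 11 HDAC genes, 3 rose and 3 fell with each compound (the same adjusted over the list alone, camera adjusted p = 0.888, 0.984 and 0.913). HDAC3 rose by 0.50, 0.69 and 0.72. Of the 15 Wnt target genes, 5, 2 and 3 rose and 5, 5 and 7 fell (the same adjusted over the list alone, camera adjusted p = 0.984, 0.638 and 0.317). The Wnt antagonist DKK1 rose by 1.43, 1.29 and 0.91, and RNF43, a ubiquitin ligase that removes Wnt receptors, changed by -1.36, -1.72 and -2.79. Of the 21 immediate-early genes, 9, 8 and 9 rose and 6, 7 and 8 fell (9, 8 and 9 higher and 6, 8 and 9 lower adjusted over the list alone, camera adjusted p = 0.322, 0.528 and 0.888). FOS rose by 2.56, 2.68 and 3.39 and its relative FOSL1 changed by -1.73, -1.74 and -2.08. Of the 20 interferon-stimulated genes, 5 rose with each compound and 8, 9 and 10 fell (5, 5 and 5 higher and 9, 9 and 10 lower adjusted over the list alone, camera adjusted p = 0.715, 0.497 and 0.527). IRF7, a regulator of interferon genes, rose by 2.69, 2.04 and 3.65, and PARP9 changed by -1.71, -1.49 and -1.62. Of the 16 antigen presentation genes, 4, 4 and 6 rose and 3, 4 and 3 fell (5, 4 and 7 higher and 5, 4 and 3 lower adjusted over the list alone, camera adjusted p = 0.836, 0.769 and 0.589). The immunoproteasome gene PSMB9 rose by 1.12, 1.12 and 1.12, and TAPBP changed by -0.79, -1.01 and -0.88. Of the 17 heat shock genes, 2 rose with each compound and 4, 5 and 6 fell (2, 2 and 2 higher and 3, 5 and 6 lower adjusted over the list alone, camera adjusted p = 0.589, 0.513 and 0.570). DNAJB1 rose by 1.44, 1.63 and 2.09. Of the 23 unfolded protein and ATF4 response genes, 9, 9 and 10 rose and 5, 7 and 6 fell (10, 9 and 11 higher and 5, 7 and 6 lower adjusted over the list alone, camera adjusted p = 0.279, 0.561 and 0.270). ATF3 rose by 1.29, 1.13 and 1.40, and SLC7A11, the cystine transporter, changed by -2.21, -1.87 and -2.31. Of the 17 thioredoxin and NRF2 response genes, 5 rose with each compound and 5, 5 and 7 fell (5, 5 and 5 higher and 6, 5 and 7 lower adjusted over the list alone, camera adjusted p = 0.984, 0.984 and 0.644). AKR1C3 rose by 2.50, 2.47 and 2.11, and ME1 changed by -0.79, -0.86 and -0.83.

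Of the 14 mesenchymal genes, 5 rose with each compound and 4, 5 and 5 fell (5, 5 and 5 higher and 5, 6 and 5 lower adjusted over the list alone, camera adjusted p = 0.637, 0.759 and 0.773). SNAI2 rose by 3.96, 3.65 and 3.98, and CALD1 changed by -0.73 with SAHA and -0.76 with FK228. Of the 24 epithelial junction genes, 6 rose with each compound and 8, 9 and 10 fell (6, 6 and 7 higher and 8, 9 and 10 lower adjusted over the list alone, camera adjusted p = 0.746, 0.817 and 0.640). DSC2, a desmosomal cadherin, changed by -2.19, -2.29 and -2.54, and the epithelial factor GRHL2 by -1.24, -1.17 and -1.69. Of the 13 intestinal differentiation genes, 3, 2 and 2 rose and 1 fell with each compound (3, 2 and 2 higher and 1, 1 and 0 lower adjusted over the list alone, camera adjusted p = 0.503, 0.589 and 0.769). CA2, a carbonic anhydrase, rose by 0.98, 0.79 and 0.88. Of the 21 glycolysis genes, 3, 3 and 6 rose and 1, 2 and 1 fell (3, 2 and 4 higher and 1, 2 and 1 lower adjusted over the list alone, camera adjusted p = 0.611, 0.681 and 0.459). ALDOC, a brain aldolase, rose by 1.16, 0.93 and 1.38. Of the 27 oxidative phosphorylation genes, 4, 3 and 4 rose and 4, 4 and 5 fell (3, 3 and 4 higher and 4, 4 and 5 lower adjusted over the list alone, camera adjusted p = 0.735, 0.764 and 0.843). NDUFC1 changed by -0.43 with SAHA and -0.40 with FK228. Of the 33 cytosolic ribosomal protein genes, 0 rose and 0 fell with each compound (the same adjusted over the list alone, camera adjusted p = 0.861, 0.746 and 0.637). Their medians were -0.021, -0.030 and -0.040, and the medians with largazole and SAHA turned positive when the arrays were scaled to equal medians of these genes. Of the 3 germline genes, 0 rose and 1 fell with each compound (the same adjusted over the list alone, camera adjusted p = 0.826, 0.888 and 0.865). PRAME, a cancer-testis antigen, changed by -0.60 with SAHA and -0.55 with FK228.

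Markers of other cell types changed in few cases. Of the 7 leukocyte markers, 1 rose and 0 fell with each compound (the same adjusted over the list alone, camera adjusted p = 0.317, 0.705 and 0.665). The actin-binding gene CORO1A rose by 2.65, 2.08 and 2.83. Of the 7 fibroblast and endothelial markers, 1 rose with each compound and 0, 1 and 0 fell (the same adjusted over the list alone, camera adjusted p = 0.715, 0.984 and 0.756). COL1A1 rose by 1.27, 0.73 and 0.60, a call that ended with FK228 without FK228 replicate 1 (adjusted p = 0.0523) or vehicle replicate 2 (adjusted p = 0.0666), and PDGFRB changed by -0.37 with SAHA. Of the 9 markers of other epithelial lines, 3, 2 and 1 rose and 0 fell with each compound (the same adjusted over the list alone, camera adjusted p = 0.300, 0.283 and 0.604). The transcription factor GATA3 rose by 2.04, 1.81 and 2.04. The median, the mean and the camera direction of a list differed in sign with largazole for germline (median 0.035, mean -0.093), Wnt target (median -0.016, mean 0.020, with the median turning positive at equal ribosomal protein medians), heat shock (median -0.14, mean 0.0059) and NRF2 response (median 0.034, mean 0.012, camera lower) genes. They did so with SAHA for HDAC (median -0.047, mean -0.019, camera higher), germline (median 0.062, mean -0.11), epithelial junction (median 0.069, mean -0.18), mesenchymal (median -0.027, mean 0.22, median positive under both scalings), leukocyte (median -0.031, mean 0.28, median positive at equal ribosomal protein medians) and NRF2 response (median -0.046, mean 0.028) genes, and with FK228 for HDAC (median -0.11, mean 0.033), germline (median 0.11, mean -0.10), epithelial junction (median 0.058, mean -0.25) and mesenchymal (median -0.046, mean 0.26) genes. With fry, which does not compare a list with other genes, 27, 25 and 27 of the 36 lists moved on balance in 1 direction and 34, 36 and 34 changed in either direction.

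The 3 inhibitors changed many genes in the same direction. All 3 raised 2348 genes and lowered 2675, among them DHRS2, NEDD9 and SNAI2 (higher) and PDE4B, HMGA2 and PCDH7 (lower), and 439 rose and 576 fell at least 2-fold with each. At least 1 compound changed 8134 genes, and 5247 were called with none. Largazole and SAHA shared 2549 rises and 2847 falls, where independent calls would share 650.1 and 784.1. For largazole and FK228 the shared calls were 2556 and 2814 (754.8 and 840.8 if independent), and for SAHA and FK228 2602 and 2951 (761.7 and 913.3). These expectations leave out the shared vehicle arrays.

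Across 13381 genes, which are not independent replicates, Pearson's r of the log2 changes was 0.967 between largazole and SAHA (Spearman's rho 0.941), 0.939 between largazole and FK228 (rho 0.903) and 0.943 between SAHA and FK228 (rho 0.908). Shared controls alone gave 0.501, 0.500 and 0.500 in the simulations. The covariances were 0.371, 0.425 and 0.443, against 0.00739, 0.00737 and 0.00737 in the simulations. With each compound set against a different vehicle array, which also leaves 1 array in place of 2 behind each change, r was 0.925, 0.904 and 0.910 and the covariance 0.363, 0.417 and 0.435.

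FK228 changed more genes at least 2-fold than the other compounds. By calls, 567 genes passed 2-fold with FK228 and not with the others, against 55 for largazole and 77 for SAHA. Among the 574 genes raised at least 2-fold by SAHA, the median change per array was 1.30 ± 0.0168 with largazole and 1.47 ± 0.0131 with FK228 (SD, n = 2), and FK228 gave the larger value for 384. Among the 753 genes lowered at least 2-fold by SAHA it was -1.25 ± 0.00114 and -1.58 ± 0.0527, and FK228 gave the larger fall for 638.

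**Figure D3:**
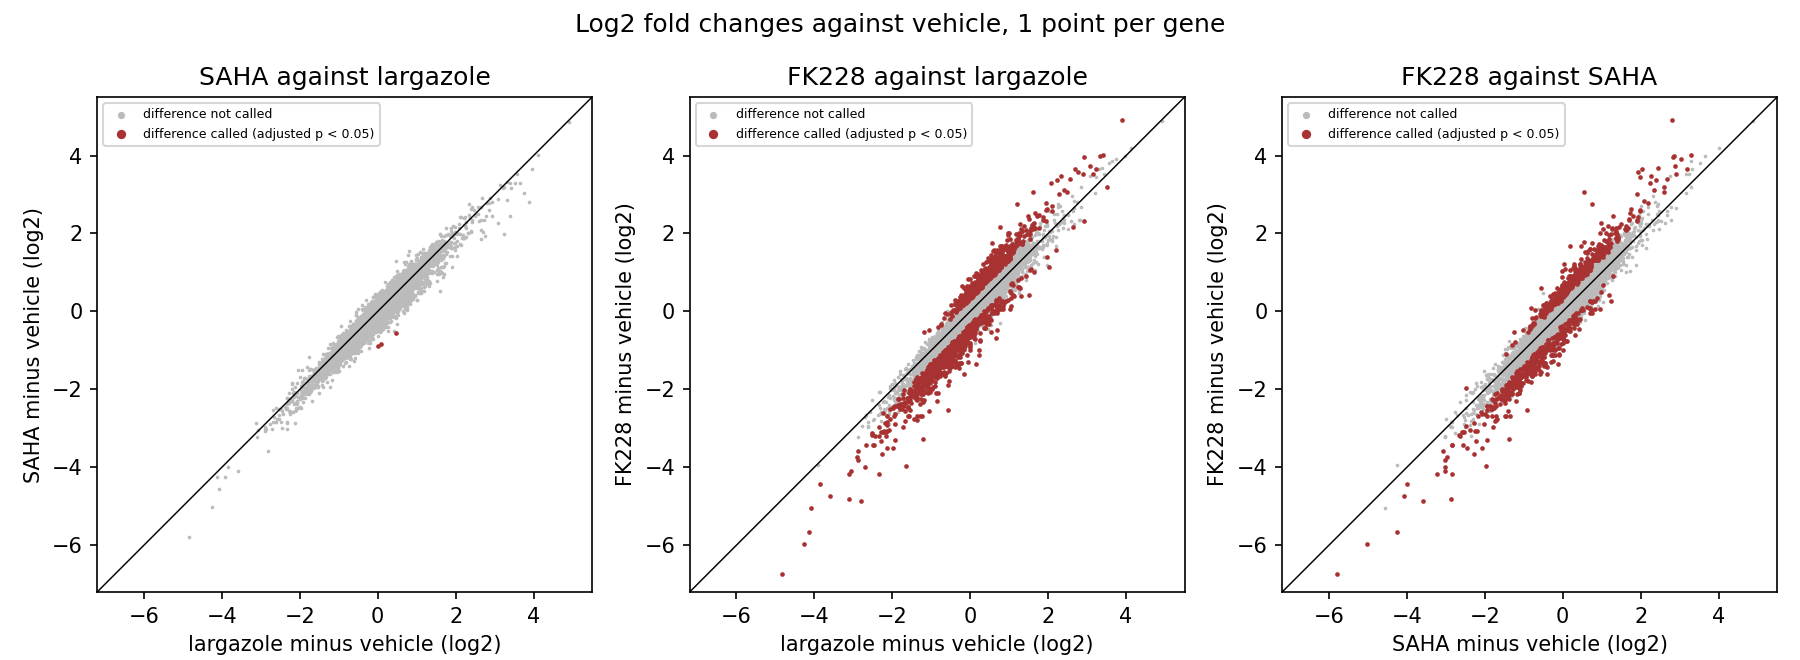
Each point is 1 gene, with its log2 change against vehicle for 1 compound on each axis, the diagonal marking equal changes and red points marking a called difference between the 2 compounds. Red points number 3 for largazole and SAHA, 1214 for largazole and FK228 and 823 for SAHA and FK228.

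Largazole and FK228, both depsipeptides at 20 nM for 10 h, differed at 1214 genes, 653 higher with largazole and 561 higher with FK228, a balance that moved with single arrays left out, to 72 and 27 without largazole replicate 1, 114 and 58 without largazole replicate 2, 189 and 144 without FK228 replicate 1 and 242 and 118 without FK228 replicate 2. At least 2-fold were 70 (59 and 11), with 57 and 18 without FK228 replicate 1 and 80 and 8 without FK228 replicate 2. Higher with largazole were TGIF1, a homeobox repressor of TGF-beta signalling, by 2.32 ± 0.089 (SE, n = 2), PHLDA1 by 2.07 ± 0.096, CYP24A1 by 2.05 ± 0.14, the ligand gene WNT16 by 1.98 ± 0.22 and PDE4B by 1.90 ± 0.12. PDE4B and CYP24A1 fell with both compounds, and further with FK228. Higher with FK228 were the antisense RNA CDKN2A-AS1 (-1.56 ± 0.17, largazole minus FK228), the microRNA host gene MIR7-3HG (-1.46 ± 0.14), the ciliary gene CFAP184 (-1.40 ± 0.088), CYSRT1 (-1.23 ± 0.091) and EHD1, an endocytic recycling ATPase (-1.21 ± 0.13). The TGIF1 value came from a probe set named _s_at, and with such probe sets left out it was 0.038 (adjusted p = 0.874), while averaging all probe sets gave 1.06 for WNT16 and 1.14 for PDE4B. The level of PDE4B (3.598) with FK228 lay under the filter value of 4.49, so the size and rank of its difference are less certain.

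In the panel, MYC was 1.03 ± 0.094 higher (SE, n = 2, adjusted p = 0.00254), CDKN1B 0.81 ± 0.12 higher, CCND1 0.47 ± 0.086 higher and MDM2 0.70 ± 0.17 higher with largazole than with FK228, and CCNE1 was lower (-0.65 ± 0.088). The CDKN1B call ended without largazole replicate 1 (adjusted p = 0.0873) or FK228 replicate 2 (adjusted p = 0.0501), the CCNE1 call without largazole replicate 1 (adjusted p = 0.0814) or largazole replicate 2 (adjusted p = 0.0516), the CCND1 call without largazole replicate 1, largazole replicate 2, FK228 replicate 1 or FK228 replicate 2 (adjusted p = 0.0644 to 0.146), and the MDM2 call without largazole replicate 1, largazole replicate 2, FK228 replicate 1, FK228 replicate 2, vehicle replicate 1 or vehicle replicate 2 (adjusted p = 0.0542 to 0.231). MDM2 was at 0.037 (adjusted p = 0.893) with probe sets named _x_at or _s_at left out. No difference was called for CDKN1A -0.084 (-0.30 to 0.13), with its unadjusted 95% confidence interval in parentheses, nor for EGFR 0.37 (0.096 to 0.64), ERBB2 0.013 (-0.18 to 0.20), ERBB3 0.086 (-0.15 to 0.32), MET 0.27 (0.014 to 0.52), IGF1R 0.23 (0.013 to 0.44), INSR -0.14 (-0.34 to 0.059), HDAC1 0.023 (-0.18 to 0.23), HDAC3 -0.22 (-0.46 to 0.017), HDAC5 -0.036 (-0.26 to 0.19), BCL2L1 0.41 (-0.14 to 0.96), MCL1 -0.31 (-0.50 to -0.12) or TYMS -0.085 (-0.27 to 0.10).

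Of the 36 lists, 4 differed between largazole and FK228. Of 40 mitosis genes, 2 were higher with largazole and 0 with FK228 (9 and 0 adjusted over the list alone), with HMMR, a spindle-associated gene, higher by 0.58. Their median was 0.21 (camera adjusted p = 3.93e-05, adjusted p = 0.314 with an estimated correlation). Of 15 Wnt target genes, 7 were higher with largazole and 0 with FK228 (the same adjusted over the list alone), with RNF43 (1.43) and AXIN2, a negative feedback regulator of the Wnt pathway (1.34), higher with largazole. Their median was 0.28 (camera adjusted p = 0.000176, adjusted p = 0.314 with an estimated correlation). The Wnt list's median was 0.44 without FK228 replicate 2 and 0.65 with the stricter filter. Of 25 ribosome biogenesis genes, 0 were higher with largazole and 4 with FK228 (the same adjusted over the list alone), with RRP9 (-0.81) and UTP20 (-0.66) higher with FK228. Their median was -0.15 (camera adjusted p = 0.00398, adjusted p = 0.314 with an estimated correlation). Of 19 cholesterol genes, 0 were higher with largazole and 1 with FK228 (0 and 3 adjusted over the list alone), with IDI1 at -0.55. Their median was -0.14 (camera adjusted p = 0.00721, adjusted p = 0.316 with an estimated correlation). With 1 array left out, the HMMR call ended without largazole replicate 1, largazole replicate 2, FK228 replicate 1 or FK228 replicate 2 (adjusted p = 0.0598 to 0.143), the RRP9 call without largazole replicate 1, largazole replicate 2 or FK228 replicate 2 (adjusted p = 0.0639 to 0.0972), the UTP20 call without largazole replicate 1 or largazole replicate 2 (adjusted p = 0.0530 to 0.0760) and the IDI1 call without largazole replicate 1, largazole replicate 2 or FK228 replicate 1 (adjusted p = 0.0552 to 0.0909).

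By probe set 2385 differed (1195 higher with largazole, 1190 with FK228), a balance that moved to 67.5% higher with largazole without largazole replicate 1, 64.8% without largazole replicate 2, 55.7% without FK228 replicate 1 and 66.3% without FK228 replicate 2, and the other way to 46.1% with the stricter filter, 49.2% with a trended robust prior and 49.5% with array weights. Of all tested, 7433 had an unadjusted p under 0.05. The count fell to 191 without largazole replicate 1, 315 without largazole replicate 2, 657 without FK228 replicate 1 and 725 without FK228 replicate 2, and it was 1058 with no filter, 1240 with the 4 arrays of the 2 groups alone, 1359 without probe sets named _x_at or _s_at, 3741 with a trended robust prior and 3587 with a replicate block.

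**Figure D4:**
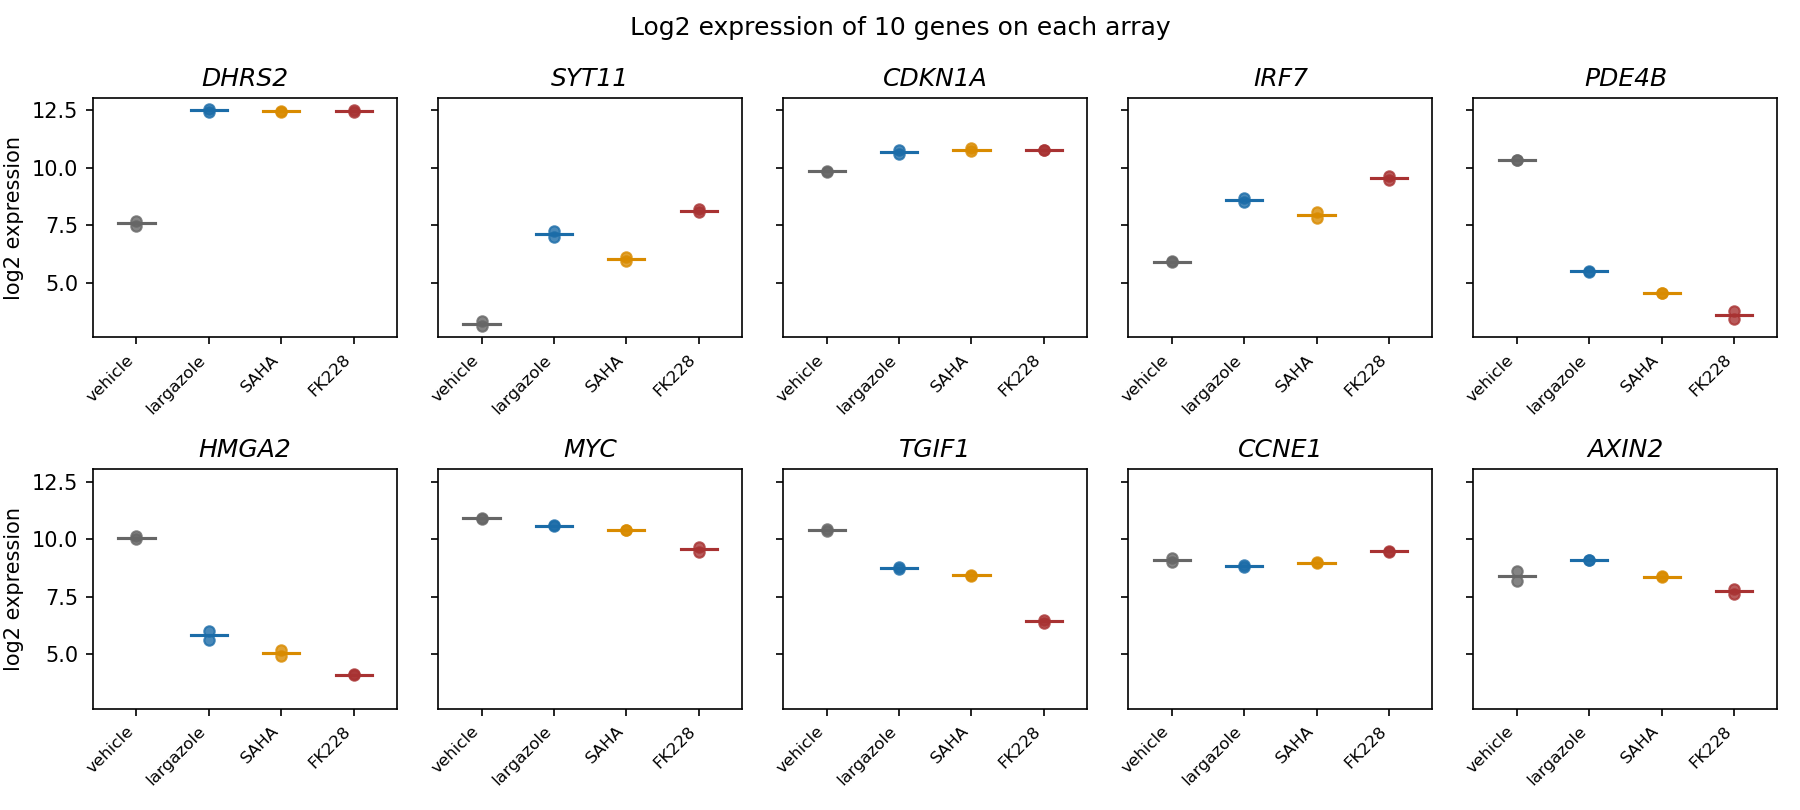
Points are log2 expression on each of the 8 arrays for 10 genes and lines are group means of 2 arrays. DHRS2 rises from 7.59 with vehicle to 12.50, 12.46 and 12.47 with largazole, SAHA and FK228, and MYC stands at 9.56 with FK228 against 10.58 with largazole.

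Largazole at 20 nM and SAHA at 2 µM, which are different doses, differed at 3 genes, each higher with largazole. These were KISS1R, the kisspeptin receptor (1.03 ± 0.10, SE, n = 2, adjusted p = 0.0386), TNFAIP2, a TNF-induced gene (0.93 ± 0.095, adjusted p = 0.0386), and PABPN1, a nuclear poly(A)-binding protein (0.88 ± 0.085, adjusted p = 0.0356). KISS1R rose with largazole (0.47) and fell with SAHA (-0.56). Each of the 3 calls ended without any 1 of the 8 arrays (adjusted p = 0.0676 to 0.338 over the 3 genes), and also with no filter (adjusted p = 0.0695 to 0.0701) and with a replicate block (adjusted p = 0.0606).

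None of the panel genes was called between largazole and SAHA. The difference, with its unadjusted 95% confidence interval in parentheses, was CDKN1A -0.089 (-0.30 to 0.12), CDKN1B -0.020 (-0.29 to 0.25), CCND1 0.050 (-0.15 to 0.25), CCNE1 -0.17 (-0.37 to 0.037), MYC 0.20 (-0.019 to 0.42), EGFR -0.23 (-0.50 to 0.041), ERBB2 0.026 (-0.16 to 0.22), ERBB3 0.0013 (-0.23 to 0.23) and MET 0.0048 (-0.25 to 0.26). It was IGF1R -0.031 (-0.25 to 0.18), INSR -0.19 (-0.39 to 0.011), HDAC1 0.059 (-0.14 to 0.26), HDAC3 -0.19 (-0.43 to 0.046), HDAC5 0.083 (-0.14 to 0.31), MDM2 0.0038 (-0.39 to 0.39), BCL2L1 -0.025 (-0.58 to 0.53), MCL1 -0.12 (-0.31 to 0.068) and TYMS 0.12 (-0.067 to 0.31) for the remaining genes.

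Wnt target genes lay higher with largazole than with SAHA, by a median of 0.20 over 15 genes (0 called, 4 higher adjusted over the list alone, camera adjusted p = 0.00398, adjusted p = 0.348 with an estimated correlation), with AXIN2 at 0.71 (adjusted p = 0.148). Metallothioneins lay lower, by a median of -0.10 over 6 genes (0 called, 0 adjusted over the list alone, camera adjusted p = 0.0314, adjusted p = 0.426 with an estimated correlation). That call ended without largazole replicate 1 (adjusted p = 0.170) or SAHA replicate 1 (adjusted p = 0.172). Neuronal genes lay higher by a median of 0.022 over 25 genes (0 called, 6 higher adjusted over the list alone, camera adjusted p = 0.0457, adjusted p = 0.412 with an estimated correlation), a call that ended without largazole replicate 1, largazole replicate 2, SAHA replicate 1, vehicle replicate 1 or vehicle replicate 2 (adjusted p = 0.0528 to 0.220). The neuronal median was 0.043 without largazole replicate 1, 0.081 without largazole replicate 2 and 0.098 without SAHA replicate 2. Among other settings, the metallothionein call ended with the stricter filter (adjusted p = 0.0550), the mean of all probe sets (0.0816) and 4 arrays alone (0.0532). The neuronal call ended with the mean of all probe sets (adjusted p = 0.0505), a further quantile normalization (0.0701), a replicate block (0.0925) and no probe sets named _x_at or _s_at (0.10), and the stricter filter moved its median to 0.046.

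By probe set limma called 11 differences between largazole and SAHA (10 higher and 1 lower with largazole), while 3584 probe sets and 1372 genes had an unadjusted p under 0.05. The count was 0 without either array of largazole or of SAHA, 3 without either FK228 array and 2 without either vehicle array. Other settings gave 6 (no filter), 108 (stricter filter), 156 (trended robust prior), 5 (replicate block), 25 (array weights), 29 (further quantile normalization) and 0 (4 arrays alone).

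FK228 at 20 nM and SAHA at 2 µM, again at different doses, differed at 823 genes, 415 higher with FK228 and 408 higher with SAHA, a near-even balance that turned to 360 and 421 at equal ribosomal protein medians, 678 and 746 with a replicate block, 791 and 803 with a trended robust prior and 282 and 316 without probe sets named _x_at or _s_at. It also turned to 42 and 52 without SAHA replicate 1, 68 and 79 without SAHA replicate 2, 84 and 86 without FK228 replicate 1 and 51 and 93 without FK228 replicate 2. Of the full set, 25 and 30 differed at least 2-fold, with 18 and 19 without SAHA replicate 1, 27 and 27 with no filter and the balance turning to 20 and 17 with the 4 arrays of the 2 groups alone. Higher with FK228 were MIR7-3HG by 2.53 ± 0.14 (SE, n = 2), SYT11 by 2.12 ± 0.13, CDKN2A-AS1 by 2.00 ± 0.17, the pseudogene CEP192P1 by 1.64 ± 0.16 and IRF7 by 1.61 ± 0.12. Higher with SAHA were TGIF1 (-2.00 ± 0.089, FK228 minus SAHA), NRIP1 (-1.97 ± 0.13), PHLDA1 (-1.91 ± 0.096), WNT16 (-1.63 ± 0.22) and ZC3H12C (-1.43 ± 0.12). CEP192P1 was at 0.58 and no longer called without FK228 replicate 1 (adjusted p = 0.0533) and at 0.98 without FK228 replicate 2, and the WNT16 call ended without SAHA replicate 1 (adjusted p = 0.0701) or FK228 replicate 2 (adjusted p = 0.0583). With probe sets named _x_at or _s_at left out TGIF1 was at -0.034 (adjusted p = 0.888), and averaging all probe sets gave -1.04 for WNT16 and -1.10 for TGIF1. Under the filter value of 4.49 lay MIR7-3HG (3.68) with SAHA and NRIP1 (4.35) and ZC3H12C (3.98) with FK228, whose differences are less certain in size and rank.

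In the panel, MYC (-0.83 ± 0.094, SE, n = 2, adjusted p = 0.00794), CDKN1B (-0.83 ± 0.12), CCND1 (-0.42 ± 0.086) and EGFR (-0.60 ± 0.12) were lower with FK228 than with SAHA and CCNE1 was higher (0.49 ± 0.088). The CDKN1B call ended without SAHA replicate 1 (adjusted p = 0.0635), FK228 replicate 1 (0.0508) or FK228 replicate 2 (0.0617). The CCND1 call ended without any 1 of the 8 arrays and the CCNE1 call without any 1 treated array. The EGFR call ended without any 1 array but FK228 replicate 2. With 4 arrays alone the MYC call ended as well (adjusted p = 0.0568). No difference was called for CDKN1A -0.0056 (-0.22 to 0.21), with its unadjusted 95% confidence interval in parentheses, nor for ERBB2 0.013 (-0.18 to 0.20), ERBB3 -0.085 (-0.32 to 0.15), MET -0.26 (-0.52 to -0.0091), IGF1R -0.26 (-0.47 to -0.044), INSR -0.049 (-0.25 to 0.15), HDAC1 0.036 (-0.17 to 0.24), HDAC3 0.029 (-0.21 to 0.27), HDAC5 0.12 (-0.11 to 0.35), MDM2 -0.70 (-1.09 to -0.31), BCL2L1 -0.44 (-0.99 to 0.11), MCL1 0.19 (-0.0042 to 0.38) or TYMS 0.21 (0.018 to 0.40).

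Of the 36 lists, 5 differed between FK228 and SAHA. Of 40 mitosis genes, 0 were higher with FK228 and 2 with SAHA (0 and 14 adjusted over the list alone), with KIF23 at -0.54 (adjusted p = 0.156). Their median was -0.23 (camera adjusted p = 4.69e-06, adjusted p = 0.314 with an estimated correlation). Of 15 Wnt target genes, 0 were higher with FK228 and 7 with SAHA (the same adjusted over the list alone), with RNF43 at -1.07 and MYC at -0.83. Their median was -0.27 (camera adjusted p = 0.00680, adjusted p = 0.354 with an estimated correlation). Of 25 neuronal genes, 3 were higher with FK228 and 0 with SAHA (4 and 0 adjusted over the list alone), with SYT11 at 2.12. Their median was 0.16 (camera adjusted p = 0.0275, adjusted p = 0.386 with an estimated correlation). Without probe sets named _x_at or _s_at the calls of the Wnt (0.0564), neuronal (0.10) and cholesterol (0.124) lists ended, with adjusted p in parentheses. The stricter filter ended the neuronal (0.257) and cholesterol (0.0568) calls and moved the Wnt median to -0.50. The neuronal call ended without SAHA replicate 1 (adjusted p = 0.0841), and the median was 0.10 without FK228 replicate 1. Of 19 cholesterol genes, 0 were higher with FK228 and 0 with SAHA (6 and 0 adjusted over the list alone), with INSIG1 at 0.52 (adjusted p = 0.0815). Their median was 0.13 (camera adjusted p = 0.0314, adjusted p = 0.354 with an estimated correlation), a call that ended without SAHA replicate 1 (adjusted p = 0.0550), FK228 replicate 1 (0.0623) or FK228 replicate 2 (0.0501). Of 6 metallothioneins, 0 were higher with FK228 and 0 with SAHA (the same adjusted over the list alone), with MT1F at -0.25 (adjusted p = 0.108). Their median was -0.17 (camera adjusted p = 0.0175, adjusted p = 0.412 with an estimated correlation), a call that ended without SAHA replicate 1 (adjusted p = 0.0526) or FK228 replicate 1 (adjusted p = 0.0790).

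By probe set 1613 differed (728 higher with FK228, 885 with SAHA), with 30.8 to 49.7% higher with FK228 over all settings, and 6931 had an unadjusted p under 0.05. The count was 198 without SAHA replicate 1, 299 without SAHA replicate 2, 339 without FK228 replicate 1, 318 without FK228 replicate 2, 771 without either largazole array and 1016 without either vehicle array. It was 652 with no filter, 2439 with the stricter filter, 925 with array weights, 138 with the 4 arrays of the 2 groups alone, 964 without probe sets named _x_at or _s_at, 2842 with a trended robust prior and 2787 with a replicate block.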

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

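The tests of the genes that still differed after scaling and of the differences taken from separate arrays were chosen only after their results were seen, and genes called in opposite directions were singled out because a difference between compounds is clearest there. With largazole and FK228, 11 genes were called in opposite directions, and for each the difference between the compounds was called as well. That adds little, as the difference of 2 opposite changes exceeds each change while its standard error stays the same. AXIN2, a negative feedback regulator of the Wnt pathway, rose with largazole (0.67) and fell with FK228 (-0.67), a difference of 1.34 (adjusted p = 0.00404). The antisense RNA ATXN1-AS1 did the same (0.69 and -0.47, difference 1.16, adjusted p = 0.00142). For these 2 genes all 3 calls held with each array left out in turn. KISS1R rose with largazole (0.47) and FK228 (0.59) and fell with SAHA (-0.56). Its difference between FK228 and SAHA (1.15) was called with each array left out, and that between largazole and SAHA (1.03) with none left out, at adjusted p = 0.0721 to 0.302 without 1 array.

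The other 9 genes lost at least 1 of their 3 calls, those against vehicle included, without any 1 of several arrays. These were all 8 arrays for CCNE1 and VKORC1L1, 6 for MCTP2 and SPOUT1 and 4 or 5 for the rest. Parentheses give the change with largazole, that with FK228 and the difference. DACT1 (0.39, -0.41, 0.80), FRMD4B (0.47, -0.33, 0.80) and LINC01003 (0.53, -0.52, 1.04) were higher with largazole. So were MCTP2 (0.27, -0.27, 0.54), PWWP3B (0.38, -0.42, 0.80) and TMX4 (0.27, -0.31, 0.58). CCNE1 (-0.27, 0.38, -0.65), SPOUT1 (-0.26, 0.30, -0.56) and VKORC1L1 (-0.26, 0.24, -0.50) were higher with FK228. The call of the difference ended without largazole replicate 1 for all 9 (adjusted p = 0.0609 to 0.104) and without largazole replicate 2 for CCNE1, DACT1, MCTP2, SPOUT1, TMX4 and VKORC1L1 (adjusted p = 0.0516 to 0.0971). It also ended without FK228 replicate 1 for MCTP2, SPOUT1 and VKORC1L1 (adjusted p = 0.0514 to 0.0569) and without FK228 replicate 2 for LINC01003, MCTP2, SPOUT1, TMX4 and VKORC1L1 (adjusted p = 0.0573 to 0.0740). VMP1, an autophagy gene, was called higher with largazole (0.42) and lower with SAHA (-0.49), but the difference of 0.91 was not called (adjusted p = 0.0572).

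More genes differed between largazole and FK228 (1214) than between largazole and SAHA (3), and a larger amplitude of 1 response with FK228 may account for part of this: with the largazole changes multiplied by 1.19, 26.3% of the 1214 genes still differed, between the bounds of 10% and 50% set for that test. The 319 genes that still differed argue against 1 common factor for them, while for the 895 no longer called the 2 accounts cannot be told apart: over the 1214 genes the median absolute difference fell only from 0.54 to 0.45 as its median standard error rose from 0.0958 to 0.106, so lost calls do not show lost differences. An outlying FK228 array as the only source is argued against: across genes, which are not independent, the lower covariance of FK228 minus largazole differences from separate arrays (0.0540, replicate numbers crossed), less the higher one of SAHA minus largazole (0.0146, replicate numbers matched), was 43.2% of the variance of 1 FK228 minus largazole difference (95% interval 41.0 to 45.1%), where an outlying array would leave under 10%. How much of the full count rests on 1 FK228 array stays open, with counts of 333 and 360 without an FK228 array but 99 and 172 without a largazole array, and 100% of genes called from 1 array of each compound keeping their direction on the other arrays, from only 8 and 3 genes. A difference between the compounds in what they act on, or in how much of each was active after 10 h, remained untested.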

How the results depend on the processing

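No alternative was added after the results were seen. Against vehicle, list results kept their side of the threshold in 1980 cases, lost their call in 64 and gained it in 5. Named genes gave 8629, 239 and 84. Most lists had no call to lose. Between compounds, lists gave 189, 37 and 0 and genes 1255, 93 and 11. With each array left out in turn, the probe set counts were 8455 to 11774 for largazole, 9860 to 12718 for SAHA and 11355 to 14271 for FK228 against vehicle, 191 to 1991 for largazole against FK228, 0 to 3 for largazole against SAHA and 198 to 1016 for FK228 against SAHA. The list shifts numbered 36 to 40, and the correlations were 0.952 to 0.967 (largazole and SAHA), 0.923 to 0.942 (largazole and FK228) and 0.923 to 0.946 (SAHA and FK228). Without probe sets named _x_at or _s_at, fewer probe sets were tested and the counts were 7125, 7612 and 8592 against vehicle, 1359 for largazole against FK228, 964 for FK228 against SAHA and 13 list shifts. With the correlation estimated per list, 0 of 40 list shifts were called, and 29 with the stricter filter. For largazole against FK228 the count was 1058 with no filter, 3741 with a trended robust prior, 3587 with replicate number as a replicate block and 1240 with 4 arrays. For largazole against SAHA it was 6 with no filter, 108 with the stricter filter, 156 with the trended prior, 5 with the replicate block, 25 with array weights, 29 after quantile normalization and 0 with 4 arrays. For FK228 against SAHA it was 652 with no filter, 2439 with the stricter filter, 2842 with the trended prior, 2787 with the replicate block, 925 with array weights and 138 with 4 arrays. The replicate block gave 13170, 13997 and 15456 probe sets against vehicle. Correlations moved to 0.953 (largazole and SAHA), 0.925 (largazole and FK228) and 0.929 (SAHA and FK228) with no filter; 0.977 (largazole and SAHA) and 0.949 (largazole and FK228) with the stricter filter; 0.925 (largazole and SAHA), 0.904 (largazole and FK228) and 0.910 (SAHA and FK228) with each compound against a different vehicle array. The fold change turned sign for INSR with largazole (0.52), FANCM with largazole (-0.095), HSPB8 with largazole (0.22), HSPB8 with SAHA (0.21) and NDUFA2 with FK228 (-0.057) without probe sets named _x_at or _s_at, POLR1A with largazole (-0.072), MACROH2A1 with SAHA (0.21) and CTSZ with FK228 (0.019) with the mean of all probe sets, and IFIT2 with largazole (0.13) with no filter. Apart from the fewer probe sets or arrays named, the cause was not tested.

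The replicate numbers may mark a shared preparation: the difference between replicate 1 and 2 correlated across genes between groups at 0.153 to 0.307, the labels state no pairing, and the replicate block is therefore an alternative (3587 probe sets between largazole and FK228). Probe sets near the filter value of 4.49 carry little signal over background, and changes of genes dim in 1 group, such as NEDD9 (2.31 with vehicle) and MKX (2.69 with FK228), depend on it.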

Other observations

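The scan of gene families by symbol root was chosen only after the gene lists had been seen, and the genes named from it were chosen after their values were seen. Among 16 intraflagellar transport (IFT) genes, which carry cargo along cilia, 11 rose with largazole (median 0.58, camera adjusted p = 0.0222, adjusted p = 0.956 with an estimated correlation) and 11 with SAHA (median 0.63, camera adjusted p = 0.0156, adjusted p = 0.956 with an estimated correlation), and none fell. With FK228 11 rose and 2 fell, and the family was not called (median 0.56, camera adjusted p = 0.0654). IFT57 rose by 0.94, 1.04 and 0.98, IFT52 by 0.84, 0.91 and 1.03 and IFT22 by 0.74, 0.89 and 1.07 with largazole, SAHA and FK228, whereas IFT74 (-0.62) and IFT81 (-0.43) fell with FK228. The IFT81 call ended without FK228 replicate 1 (adjusted p = 0.140) or vehicle replicate 1 (adjusted p = 0.147). The medians kept their sign under both scaling alternatives.

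Among 49 genes of the large subunit of the mitochondrial ribosome (MRPL), 24 fell and 3 rose with largazole (median -0.25, camera adjusted p = 0.0156, adjusted p = 0.956 with an estimated correlation). The counts were 24 and 3 with SAHA (median -0.26, camera adjusted p = 0.0586) and 20 and 4 with FK228 (median -0.16, camera adjusted p = 0.188), where the family was not called. Differences between compounds were not tested for these families. Genes whose symbol is H and a number, among them the histone genes H2BC5 and H2AC6 of the histone list, were the only family called with all 3 compounds. Of 32, 16 rose and 1 fell with largazole (median 0.35, camera adjusted p = 0.00158), 15 and 1 with SAHA (median 0.28, camera adjusted p = 0.0128) and 17 and 1 with FK228 (median 0.34, camera adjusted p = 0.0222), with adjusted p = 0.956 with an estimated correlation for each.

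The scan made 282 tests over 94 families with at least 15 members, of which 6 were called and 0 with an estimated correlation.

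Genes dim in vehicle rose more often than the brightest genes, though not in steady steps. Of 104 genes with a vehicle log2 level under 4, 68, 56 and 68 rose at least 2-fold with largazole, SAHA and FK228 and 0 fell, as the filter requires of them a higher value on treated arrays. Of 1923 genes over 10, 12, 13 and 23 rose and 65, 73 and 120 fell at least 2-fold. The rank correlation of level and change with the 2 taken from different vehicle arrays was -0.114 or further from 0 with every compound. That argues against noise of a single vehicle array, entering both level and change, as the whole account. A deviation common to the 2 vehicle arrays would stay in both and was not tested. Among 12574 genes above the filter value on both vehicle arrays it was -0.0635 with SAHA, -0.106 with largazole and -0.123 with FK228, where 1 test over all compounds asked for values within 0.05 of 0 if the filter were the cause and for values below -0.1 if not. Values with largazole and FK228 lay below -0.1 and that with SAHA did not, so the filter may account for part of the pattern and cannot be told apart from opening of silent genes, which was not tested.

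Genes next to each other on a chromosome changed slightly alike. The correlation of log2 changes over 13342 adjacent pairs was 0.0572 with largazole, 0.0578 with SAHA and 0.0755 with FK228, above the highest of 1000 shuffled gene orders (0.0239, 0.0274 and 0.0273). Leaving out the 770 pairs with the same symbol root kept the lowest value at 0.0435 (SAHA), which argues against similar sequences of clustered family members as the whole account. Shared regulation of neighbours may contribute, and the size of these correlations leaves most of the variation between genes unrelated to order.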
